A study of Homo sapiens with 12 samples.

How the data were processed

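RNA was measured in 2 parental and 2 cabozantinib-resistant Caki-1 libraries, and H3K27ac by chromatin immunoprecipitation in 2 libraries of each line. Cells for immunoprecipitation were fixed in 1% formaldehyde for 10 min, per the labels, and libraries were read as 150-bp pairs. The 4 DNA inputs were not analysed here. The submitters' processing notes name STAR, RSEM and DESeq2 1.40.2 and the builds GRCh38 and hg19, without roles. The deposited RNA tables give RSEM estimated counts and TPM for 20114 gene symbols in each of the 4 libraries. The estimated counts, of which 3.16% were fractional, were rounded to whole numbers. The deposited TPM values were used for effective gene length and for 2 alternatives. The deposited peak lists hold 1 list per library with a position and a score per peak. The peak caller, the use of the inputs and the meaning of the score are not given in the sources used here. The score has no named unit and a minimum just above 2. It took the place of the fold enrichment and the q-value that had been planned for ranking and filtering peaks. Peaks on chromosome 1 end at up to 249240417, beyond the length of that chromosome in GRCh38, and the coordinates were read as hg19.

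Samples were grouped by their titles. Library totals were 10605113, 10584083, 14664723 and 12851393 counts. The parental pair differed by more than sampling noise (1.95 per gene in a chi-square statistic) and was kept as 2 replicates. Genes were kept by filterByExpr, which left 12792, scaled by TMM in edgeR 4.0.16 (R 4.3.3) and tested with the quasi-likelihood F test, line as the only term and Benjamini-Hochberg adjustment at 0.05. Levels are TMM-scaled read counts relative to library size (CPM), and a change is the resistant over the parental line. A gene at 0 in both libraries of a line is compared with a floor of 3 counts over the group, and with 1 to 3 counts the ratio has an exact 95% binomial counting interval. The 28 date-like symbols, which a spreadsheet had altered, stayed in the fit and were not named.

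The samples' groups, the main test, the 26 gene lists, the rule for named genes and all alternatives but the 3 named as added below were fixed before the data were examined. The lists had 552 entries, of which 551 were in the tables. They were AXL and MET receptors with family and ligands, cabozantinib target kinases, other receptor tyrosine kinases, growth factor ligands, ERK pathway output, mesenchymal genes, epithelial genes, YAP and TEAD targets, hypoxia genes, cholesterol synthesis, lysosome genes, integrated stress response, ER chaperones and unfolded protein response, NRF2 targets, interferon-stimulated genes, antigen presentation, NF-kB targets and inflammatory cytokines, proliferation genes, p53 targets, BCL2 family and IAP genes, drug transporters and metabolism, kidney tubule genes, integrins, markers of blood, endothelial and stromal cells, mitochondrially encoded mRNAs, and immediate early genes. Some genes are in more than 1 list. Lists were tested with camera at a preset correlation of 0.01 (limma 3.58.1), with camera at an estimated correlation and with fry.

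The rule for named genes took AXL and MET and, among genes past the threshold with a mean log2 CPM of 2 or more and both resistant libraries on the same side of both parental ones, the 10 largest rises and 10 largest falls of protein-coding symbols. It also took up to 2 rises and 2 falls from each list, or the 2 most abundant members where none passed. Of the genes this rule took, 2 are not reported here. Other members of short sets of calls, and FN1, AHR, CD68 and EGFR, were named after their values were seen. Named regions were the 5 gained and 5 lost with the highest weaker score. The rule's regions near AXL and MET, the nearest gene of each region and the test of genes near gained and lost regions were not run, since the gene table used here is in GRCh38 and no coordinates were converted between builds. That table (GRCh38.p14) served only for gene order, and 12575 of the 12792 tested genes matched it.

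Peaks that overlapped by at least 1 bp in any of the 4 lists were merged into regions with Python 3.11.15 and pandas 2.3.3. A region was gained with a peak in both resistant and neither parental library, and lost in the reverse case. The other 2 ways to split the libraries into pairs gave the background. The alternatives were DESeq2 size factors, library totals, no filter beyond 1 count, a filter at a mean log2 CPM of 2, DESeq2 1.42.0's Wald test, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes at a TPM of 1 or more in 2 libraries, a term for the replicate number, a threshold of 0.01, and leaving out each library. For peaks they were a score of 5 or more, the 52367 best peaks of each list, cover of 50% of a region, merging within 500 bp, and leaving out each library. Correction for effective length (a lowess trend of span 0.3 per library entered as offsets, for 12511 genes with a length from counts of 20 or more), sample quality weights and single replicate numbers of the peaks were added after the data were seen.

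The calculations were tested on simulated data. For 12792 genes simulated from the means and depths of the resistant against parental comparison, the test called 46% of 100 genes changed 2-fold and 98% of 100 genes changed 4-fold, with 2 unchanged genes called. Changes were planted only in genes with a mean above 4 CPM. Both lines were given the same spread per gene, while the real resistant libraries differed more than the parental ones. With a length trend added to 1 library it called 113 of the 200 changed genes and 4 unchanged ones, and 163 and 14 after correction. In 6000 simulated regions of the gained and lost comparison all 6 planted patterns were recovered exactly.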

Results

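RNA and the histone mark H3K27ac, an acetylation found at active promoters and enhancers, were measured in Caki-1, an established human renal cell carcinoma line, and in a cabozantinib-resistant derivative of it. Cabozantinib is a kinase inhibitor whose targets include MET, AXL and the VEGF receptors. The resistant line was selected with 5 µM of the drug, raised to 20 µM within 2 months, and was afterwards kept in 10 µM. The parental cells were kept in RPMI medium and the resistant cells were selected in McCoy's medium, so drug exposure, medium and selection differ together between the lines. Of 12 samples, 4 were RNA libraries, 4 were H3K27ac libraries and 4 were DNA inputs, with 2 of each kind per line. The inputs were not analysed here. The RNA libraries held 10605113 and 10584083 estimated counts in the parental line and 14664723 and 12851393 in the resistant line. The H3K27ac lists held 54810 and 57975 peaks in the parental line and 52367 and 52856 in the resistant line. The labels do not say that replicates came from separate cultures, so p-values of single genes measure only the spread between these libraries. With camera the p-values compare listed genes with the other genes. Those from random gene sets or permuted chromosomes measure spread over genes or chromosomes within these same libraries.

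The study's title names AXL and MET, the receptors for GAS6 and HGF, and the first comparison asked whether their mRNA differed between the lines. AXL stood at 214 ± 4.61 CPM, the normalised read count (SD, n = 2), in the parental line and at 145 ± 9.21 in the resistant line, a log2 fold change of -0.56 ± 0.14 (SE), and was lower in both resistant libraries. Its adjusted p of 0.0706 missed the threshold of 0.05. MET stood at 545 ± 12.4 CPM in the parental line and 410 ± 127 in the resistant line (log2 fold change -0.41 ± 0.23, adjusted p = 0.301). The AXL ligand GAS6 stood at 368 ± 30.4 and 192 ± 52.7 CPM (log2 fold change -0.94 ± 0.22, adjusted p = 0.0611). The other 3 measured members of this receptor and ligand list had log2 fold changes of 0.30 (TYRO3), -0.27 (MERTK) and -0.21 (PROS1). Of its 6 measured members 0 passed with edgeR over all genes tested, while 2 had an unadjusted p under 0.05 and 2 were lower with DESeq2. Adjusted over the list alone, AXL and GAS6 fell (adjusted p = 0.0193 for both). The list did not pass camera's test (median log2 fold change -0.34, adjusted p = 0.176). Of 4 measured cabozantinib target kinases 0 passed with edgeR over all genes, while 1, AXL, had an unadjusted p under 0.05, was lower with DESeq2 and fell when adjusted over the list alone. That list did not pass camera's test either (median -0.34, adjusted p = 0.426). Its 4 measured members, AXL, MET, MERTK and TYRO3, are all in the receptor and ligand list too, so this is not a separate result. The other targets of the 14 listed, the VEGF receptors included, were not among the genes tested. Adjusted p for AXL was 0.0472 with DESeq2, 0.00131 without resistant replicate 1 and 0.00276 without resistant replicate 2, and it ranged from 0.00131 to 0.719 over all alternatives. MET passed only without resistant replicate 1 (log2 fold change -0.76, adjusted p = 0.000697), and stood at 500 and 321 CPM in the resistant libraries. GAS6 passed without resistant replicate 1 (adjusted p = 0.00316) and without resistant replicate 2 (0.0011), and with DESeq2 (0.00139), limma-trend on TPM (0.027 and 0.0321), a replicate block (0.00142), sample quality weights (0.00268) and length correction (0.0147).

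**Figure D1:**
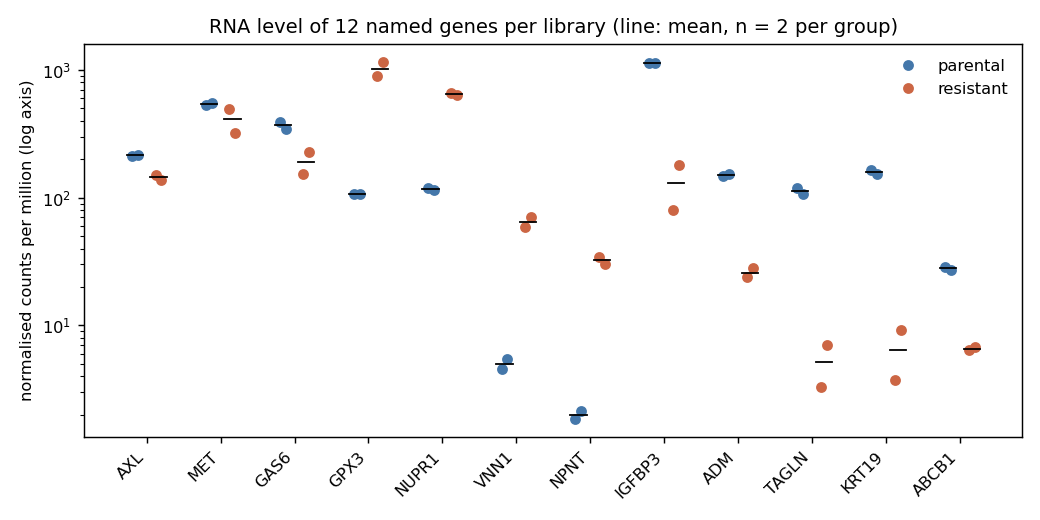
Normalised read counts (CPM, log axis) of 12 named genes in each of the 4 RNA libraries, with 1 point per library and a line at the mean of each group. AXL lies at 211 and 217 in the parental libraries and at 152 and 139 in the resistant ones, while ABCB1 lies at 28.9 and 27.1 against 6.40 and 6.76.

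Across the transcriptome several transcripts of the parental line had 0 counts in the resistant line, and others rose. MMP2, a secreted gelatinase, stood at 47.6 ± 3.42 CPM (SD, n = 2) in the parental line and had 0 counts in both resistant libraries, at least 450-fold lower against a floor of 3 counts over the group. MT1E, SLC17A9 and IRX5 likewise had 0 counts in both resistant libraries, at least 128-fold, 124-fold and 106-fold lower. MMP2, IRX5 and MT1E are near each other on chromosome 16, so their falls need not be independent. MMP2 and IRX5 lie in the same window of 25 neighbouring tested genes, from ITFG1 to MT2A, and MT1E opens the next. In the window of MMP2 and IRX5 5 genes fell and 0 rose, and the median log2 fold change was -0.17. GPX3, a secreted glutathione peroxidase, rose from 106.5 ± 0.556 to 1027 ± 187 CPM. VNN1, a pantetheinase, rose from 5.00 ± 0.602 to 64.9 ± 8.45, and NPNT, an extracellular matrix protein of kidney development, from 1.99 ± 0.20 to 32.3 ± 2.66. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 379 genes higher and 436 lower among 12792 tested, and 3455 genes had an unadjusted p under 0.05. Of these calls 279 were higher and 330 lower by 2-fold or more. With library totals in place of TMM factors the split turned to 531 higher and 373 lower.

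The other large rises were CHRDL1, a BMP antagonist, at 15.5 ± 0.462 CPM in the resistant line against 0.146 ± 0.0692, and ZMAT1, LHX1, MYH14, CCDC69, ITPKA and CES4A, with log2 fold changes from 5.30 down to 3.13. CHRDL1 had 3 counts in the parental pair, so its ratio of 106 has a counting interval of 36.1 to 517. LHX1, a transcription factor of kidney development, stood at 0.583 ± 0.139 and 11.9 ± 6.18 CPM. The other large falls were MEGF6, UNC13C, FAM101A, CPXM1 and PDE10A. MEGF6 had 3 counts in the resistant pair and a ratio of 415, with an interval of 142 to 2020, and UNC13C had 1 count and an interval of 74.6 to 16600. CPXM1 had 3 counts and an interval of 26.6 to 386. PDE10A, a cyclic nucleotide phosphodiesterase, fell from 19.4 ± 0.969 to 0.427 ± 0.494 CPM and FAM101A from 35.3 ± 4.37 to 0.421 ± 0.0454. DNAJC25-GNG10, a read-through transcript that shares reads with its parts, and MT1E, one of several near-identical metallothionein genes, are uncertain. The intervals and floors cover counting error only.

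The counts of calls depended on which library was left out, with 3374 higher and 3479 lower genes without resistant replicate 1 and 2072 and 2487 without resistant replicate 2. Without parental replicate 1 they were 154 and 270, and without parental replicate 2 they were 141 and 264, the lone library being assumed to vary like the pair of the other group.

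Of 26 gene lists, 11 passed camera's test at an adjusted p under 0.05, 7 of them lower and 4 higher in the resistant line. With an estimated correlation between genes 0 lists passed, and 3 had an unadjusted p under 0.05. That correlation was -0.016 in mesenchymal genes, -0.02 in integrated stress response and -0.0434 in growth factor ligands, below the preset 0.01. In these lists it was therefore not correlation between genes that ended the call. In the other lists that passed at the preset it was above 0.01. This setting takes its degrees of freedom from the 4 RNA libraries, so it could hardly pass any list and decides little. fry, which asks whether a list's genes move 1 way on balance, passed 4 lists: mesenchymal genes, AXL and MET receptors with family and ligands, markers of blood, endothelial and stromal cells, and growth factor ligands.

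Of 20 measured mesenchymal genes, 7 fell, 0 rose and 13 did not pass (camera adjusted p = 3.66e-09; adjusted p = 0.392 with an estimated correlation). TAGLN, an actin-binding protein of smooth muscle, fell from 113 ± 8.53 to 5.14 ± 2.61 CPM. Fibronectin, FN1, singled out after its values were seen, fell from 31640 ± 908 to 2718 ± 1300 and took 3.13% and 3.02% of all counts in the parental libraries against 0.384% and 0.180%. When adjusted over the list alone, 12 fell and 1 rose. Markers of blood, endothelial and stromal cells were measured for 5 genes, of which 3 fell and 2 did not pass (adjusted p = 7.1e-07; adjusted p = 0.392 with an estimated correlation), and 4 fell when adjusted over the list alone. The 3 that fell over all genes were DCN, a matrix proteoglycan, at 12.6 ± 0.922 and 0.634 ± 0.567 CPM, RGS5 at 19.9 ± 0.212 and 5.68 ± 0.0132, and CD68, a lysosomal glycoprotein of macrophages, at 86.6 ± 2.61 and 42.8 ± 2.90 (named after its value was seen).

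Hypoxia genes had 9 members lower, 0 higher and 12 that did not pass, of 21 measured (adjusted p = 5.37e-07; adjusted p = 0.508 with an estimated correlation). ADM, the vasodilator peptide adrenomedullin, fell from 151 ± 2.48 to 25.96 ± 3.06 CPM, and PDK1, a kinase that inhibits pyruvate dehydrogenase, from 41.9 ± 1.85 to 14.2 ± 1.38, and 12 members fell and 1 rose when adjusted over the list alone. Of 24 measured NF-kB targets and inflammatory cytokines, 5 fell, 0 rose and 19 did not pass (adjusted p = 1.33e-07; adjusted p = 0.508 with an estimated correlation), and 9 fell when adjusted over the list alone. PTGS2, the inducible cyclooxygenase, fell from 25.9 ± 2.69 to 3.09 ± 1.95 CPM, and the chemokine CCL2 had 0 counts in both resistant libraries, at least 23.4-fold lower. CXCL6, IL1A and IL1B were the other members that fell (log2 fold changes -2.85, -2.46 and -1.58). The median log2 difference of this list from the parental mean was -0.69 in resistant replicate 1 and -2.06 in resistant replicate 2.

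Of 21 measured YAP and TEAD targets, 5 fell, 1 rose and 15 did not pass (adjusted p = 1.44e-06; adjusted p = 0.508 with an estimated correlation). The median log2 difference of the list was -0.09 in resistant replicate 1 and -0.65 in resistant replicate 2, and the median log2 fold change went from -0.34 to -0.19 after correction for effective length. IGFBP3, an insulin-like growth factor binding protein, fell from 1134 ± 8.74 to 130 ± 70.0 CPM and ANKRD1 from 11.1 ± 0.0335 to 1.75 ± 0.273. FOXF2, a forkhead transcription factor, had 0 counts in both parental libraries and was at least 7.01-fold higher in the resistant line, a call that ended without either parental library (adjusted p = 0.122 and 0.120). CCDC80, TGFB2 and CRIM1 fell as well (log2 fold changes -2.23, -2.19 and -2.01), and 8 members fell and 1 rose when adjusted over the list alone. Among 18 measured genes of ER chaperones and unfolded protein response, 2 fell, 0 rose and 16 did not pass (adjusted p = 0.0175; adjusted p = 0.508 with an estimated correlation), and 3 fell when adjusted over the list alone. HSP90B1 fell from 1390 ± 12.9 to 730 ± 136 CPM and PDIA6 from 720 ± 11.8 to 405 ± 68.3, but neither passed without either parental library (adjusted p from 0.303 to 0.438).

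Growth factor ligands had 1 member higher, 6 lower and 16 that did not pass, of 23 measured (adjusted p = 0.0302; adjusted p = 0.508 with an estimated correlation). Their median log2 fold change was 0.00, their mean -0.34 and camera's direction down, and the call ended without resistant replicate 1 (adjusted p = 0.189) and without parental replicate 1 (0.122), and with limma-voom, sample quality weights, a replicate block and length correction (0.0701 to 0.0786). EGF rose from 4.37 ± 0.261 to 15.0 ± 5.44 CPM. TGFB2 fell from 28.1 ± 0.667 to 6.17 ± 0.699, and FGF1 had 3 counts in the resistant pair, with a ratio of 21.1 and an interval of 6.79 to 106. When adjusted over the list alone, 2 rose and 7 fell.

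Of 20 measured genes of the integrated stress response, the program driven by ATF4, 5 rose, 0 fell and 15 did not pass (adjusted p = 0.000117; adjusted p = 0.392 with an estimated correlation). NUPR1, a stress-induced chromatin regulator, rose from 117 ± 2.77 to 647 ± 21.6 CPM and PHGDH, the first enzyme of serine synthesis, from 79.9 ± 7.60 to 240 ± 30.1. PSAT1, TRIB3 and CEBPB rose as well (log2 fold changes 1.51, 0.93 and 0.79), and 6 members rose when adjusted over the list alone. NRF2 targets had 6 members higher, 1 lower and 16 that did not pass, of 23 measured, with the same counts adjusted over the list alone (adjusted p = 0.0175; adjusted p = 0.653 with an estimated correlation). PIR rose from 22.8 ± 0.416 to 65.4 ± 3.66 CPM and OSGIN1 from 18.2 ± 2.53 to 64.2 ± 17.7. AKR1B10, an aldo-keto reductase with close paralogs, fell from 78.4 ± 1.61 to 11.4 ± 5.56. The median log2 difference of NRF2 targets was 0.52 in resistant replicate 1 and -0.06 in resistant replicate 2, and the call ended without resistant replicate 1 (adjusted p = 0.614) or without either parental library (0.0651 and 0.0758), after correction for effective length (0.0563, median log2 fold change 0.38 before and 0.21 after) and with fry (0.302).

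Proliferation genes passed as a list (adjusted p = 6.92e-05; adjusted p = 0.588 with an estimated correlation), although 0 of 25 measured members passed alone with edgeR, over all genes or adjusted over the list alone. With DESeq2 6 members rose, and 15 had an unadjusted p under 0.05, higher in the resistant line. BIRC5, the inhibitor of apoptosis survivin, stood at 70.4 ± 0.910 and 121 ± 44.9 CPM, and TK1 at 128 ± 0.887 and 185 ± 72.4. BIRC5 passed without resistant replicate 1 (adjusted p = 0.000521) or 2 (0.0163), with DESeq2 (0.0454), sample quality weights (0.0217) and a replicate block (0.0218), and TK1 without resistant replicate 1 (0.000551). The median log2 difference of the list was 0.33 in resistant replicate 1 and 0.84 in resistant replicate 2. Of 13 mitochondrially encoded mRNAs, 1 rose, 0 fell and 12 did not pass (adjusted p = 0.00262; adjusted p = 0.508 with an estimated correlation), and 6 rose when adjusted over the list alone. MT-CO2, a subunit of cytochrome c oxidase with nuclear pseudogene copies, rose from 6115 ± 33.1 to 14250 ± 3750 CPM, a call that ended without either parental library (adjusted p = 0.165 and 0.184). All mitochondrial genes together took 5.08% and 5.20% of the counts in the parental libraries and 7.72% and 9.57% in the resistant ones.

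Outside the AXL and MET receptors and the cabozantinib targets, 13 more lists did not pass camera's test. Drug transporters and metabolism had 1 member higher, 2 lower and 15 that did not pass (list adjusted p = 0.485). ABCB1, the efflux pump P-glycoprotein, fell from 28.0 ± 1.26 to 6.58 ± 0.253 CPM and ABCA3, a lipid transporter, from 52.8 ± 4.84 to 25.2 ± 0.663. UGT1A1, a glucuronosyltransferase that shares exons with its gene family and is uncertain, rose from 14.4 ± 0.183 to 38.0 ± 1.17. The call of ABCA3 ended without parental replicate 1 (adjusted p = 0.189) or 2 (0.0729). When adjusted over the list alone, 1 rose and 3 fell. Of 18 measured epithelial genes, 1 rose, 4 fell and 13 did not pass (list adjusted p = 0.0601), with 3 higher and 6 lower adjusted over the list alone. KRT19, a simple-epithelium keratin, fell from 159 ± 6.82 to 6.46 ± 3.83 CPM and DSP, a desmosome protein, from 7.58 ± 0.80 to 2.10 ± 0.327, and the desmosome genes PKP2 and PKP3 fell too (log2 fold changes -1.04 and -0.95). SPINT1, a protease inhibitor, rose from 7.0 ± 1.67 to 21.8 ± 5.56. Without parental replicate 2 the calls of DSP (adjusted p = 0.0779) and SPINT1 (0.0651) ended. The epithelial list itself passed, lower, without resistant replicate 2 (adjusted p = 0.00332), parental replicate 1 (0.0239) or parental replicate 2 (0.00496).

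Kidney tubule genes had 3 members higher, LHX1, CDH16 and ANPEP, 0 lower and 9 that did not pass (list adjusted p = 0.225). CDH16, a kidney cadherin, rose from 6.07 ± 1.97 to 17.4 ± 4.10 CPM, a call that ended without parental replicate 1 (adjusted p = 0.155). When adjusted over the list alone, 4 rose and 2 fell. Among 17 measured other receptor tyrosine kinases, 3 rose, 2 fell and 12 did not pass (list adjusted p = 0.883), with 3 and 3 adjusted over the list alone. FGFR3, a fibroblast growth factor receptor, rose from 4.57 ± 0.0145 to 15.7 ± 6.02 CPM and FGFR4 from 64.8 ± 2.47 to 151 ± 53.6, and FGFR1 rose too (log2 fold change 1.06). The ephrin receptor EPHB2 fell from 494 ± 15.8 to 286 ± 27.8 and RYK, a WNT receptor, from 98.6 ± 0.381 to 59.0 ± 6.39. The calls of FGFR4, EPHB2 and RYK ended without either parental library (adjusted p from 0.0875 to 0.488).

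Lysosome genes had 3 members higher, 2 lower and 21 that did not pass (list adjusted p = 0.143), and 7 and 2 adjusted over the list alone. GPNMB, a lysosomal glycoprotein, rose from 9.91 ± 0.793 to 20.8 ± 2.54 CPM and GLA, a galactosidase, from 19.5 ± 0.955 to 38.6 ± 2.88, and the sialidase NEU1 rose too (log2 fold change 0.70). PSAP, the saposin precursor, fell from 2706 ± 48.6 to 1433 ± 136 and the protease CTSB from 1500 ± 27.1 to 897 ± 44.1. The calls of GPNMB, GLA, PSAP and CTSB ended without either parental library (adjusted p from 0.189 to 0.564), and the list passed, higher, without resistant replicate 2 (0.0141). Immediate early genes had 1 member higher, KLF4, 1 lower, DUSP1, and 16 that did not pass (list adjusted p = 0.855), with the same counts adjusted over the list alone. DUSP1, a MAP kinase phosphatase, fell from 102 ± 1.08 to 40.9 ± 7.08 CPM, and KLF4, a transcription factor, rose from 2.72 ± 0.00861 to 7.01 ± 0.790.

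Interferon-stimulated genes had 1 member higher, IFI35, at 25.5 ± 0.355 and 51.5 ± 9.30 CPM, 1 lower, IFI27, at 12.9 ± 1.00 and 1.86 ± 0.889, and 23 that did not pass (list adjusted p = 0.426), with 1 and 2 adjusted over the list alone. Neither IFI35 nor the immediate early gene KLF4 passed without either parental library (adjusted p from 0.230 to 0.279). Of 16 measured integrins 1 fell, ITGB8, from 85.0 ± 3.99 to 37.7 ± 2.90 CPM, and 15 did not pass (list adjusted p = 0.169), with 1 higher and 4 lower adjusted over the list alone. The call of ITGB8 ended without parental replicate 2. The integrin list passed, lower, only without resistant replicate 1, where the resistant line rested on replicate 2. Its median log2 difference was 0.04 in resistant replicate 1 and -0.68 in resistant replicate 2. After correction for effective length the integrin list did not pass camera's test (adjusted p = 0.453). Of 20 measured p53 targets 1 fell, ZMAT3, an RNA-binding protein, from 94.3 ± 1.69 to 38.4 ± 9.65 CPM, and 19 did not pass (list adjusted p = 0.143), with 2 lower adjusted over the list alone. That list passed, lower, after correction for effective length (adjusted p = 0.0224).

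Antigen presentation, cholesterol synthesis, ERK pathway output and BCL2 family and IAP genes had 0 members past edgeR's threshold over all genes, of 17, 22, 18 and 18 measured. In the same order, 4, 8, 2 and 6 members had an unadjusted p under 0.05, and DESeq2 called 1, 0, 0 and 3. Adjusted over the list alone, 0 members of antigen presentation, cholesterol synthesis and ERK pathway output passed, and 1 BCL2 family and IAP gene rose and 2 fell. The list adjusted p was 0.259, 0.224, 0.851 and 0.743. B2M, the light chain of MHC class I, stood at 718 ± 12.1 and 709 ± 116 CPM. Without resistant replicate 1 antigen presentation and cholesterol synthesis passed, higher, a comparison that rested on resistant replicate 2. The median log2 difference of antigen presentation was -0.07 in resistant replicate 1 and 0.43 in resistant replicate 2. For cholesterol synthesis it was 0.08 and 0.32. After correction for effective length neither list passed camera's test (adjusted p = 0.451 and 0.153). B2M turned direction with the library left out, with a log2 fold change of 0.14 without resistant replicate 1 and -0.20 without resistant replicate 2. The cholesterol enzyme FDPS stood at 86.3 ± 1.99 and 127 ± 31.5 CPM. IER3 stood at 527 ± 5.48 and 446 ± 46.3, the cyclin CCND1 at 293 ± 8.28 and 290 ± 9.58, MCL1, a survival factor, at 245 ± 2.77 and 208 ± 11.7, and BAX, a mediator of cell death, at 166 ± 6.5 and 159 ± 33.7. Without resistant replicate 1 or 2, where the spread came from the parental pair, B2M (adjusted p = 0.028 and 0.0162), FDPS (0.000986 and 0.0236), IER3 (0.0336 and 0.00347) and MCL1 (0.00571 and 0.0258) passed, and BAX passed without resistant replicate 2 (0.0165). IER3 passed after length correction too (0.0235).

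The median and mean log2 fold change and camera's direction differed in sign in some of these lists. Medians, means and directions were 0.01, -0.02 and down for drug transporters, -0.10, 0.08 and down for immediate early genes, -0.05, 0.03 and up for ERK pathway output, and -0.04, 0.12 and up for other receptor tyrosine kinases.

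**Figure D2:**
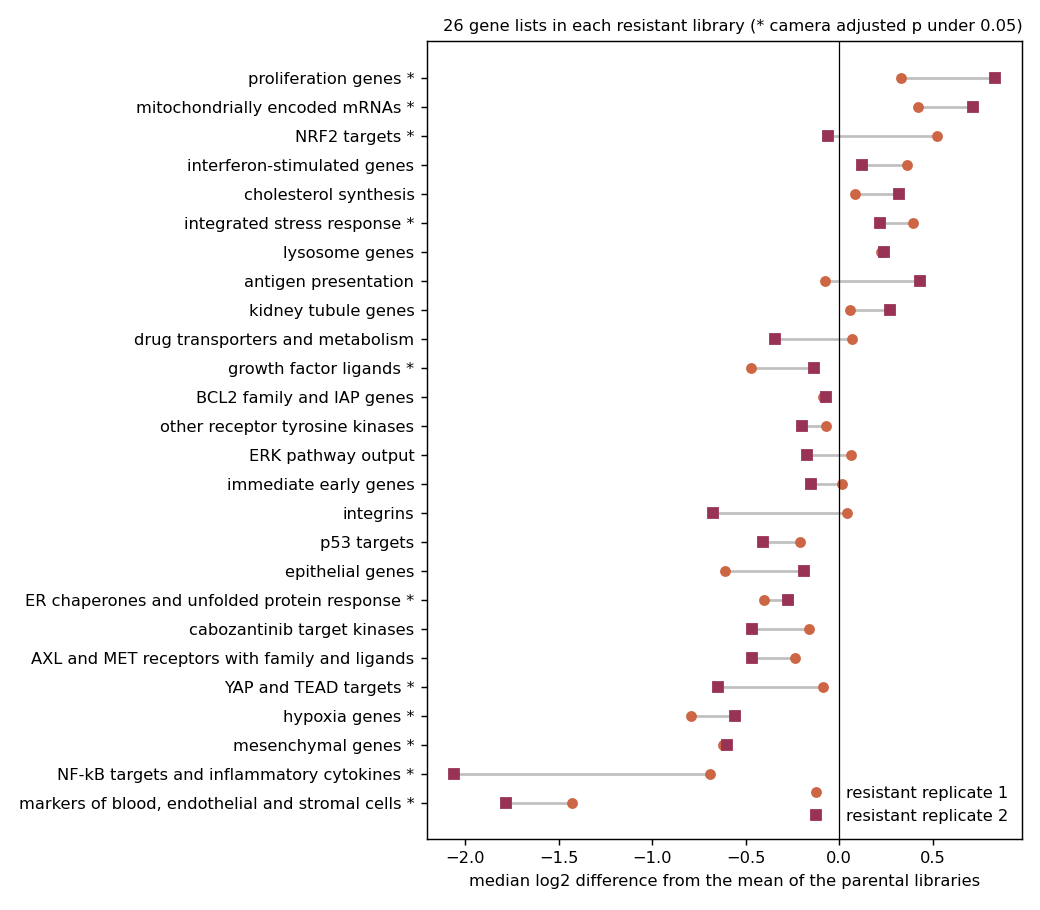
Median log2 difference of each of the 26 gene lists from the mean of the parental libraries, with a circle for resistant replicate 1 and a square for resistant replicate 2; an asterisk marks an adjusted p under 0.05 with camera. NF-kB targets lie at -0.69 and -2.06, and mesenchymal genes at -0.62 and -0.60.

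The resistant RNA libraries differed from each other more than the parental ones did. A chi-square statistic of their counts came to 48.5 per gene over 12799 genes, against 1.95 per gene over 12474 genes in the parental pair. In resistant replicate 2 transcript levels fell with effective gene length: across genes, which are not independent replicates, the rank correlation of its log2 difference from the parental mean with length was -0.46, against -0.013 for resistant replicate 1. The median log2 difference of resistant replicate 2 from the parental mean ran from 0.45 in the decile of shortest genes to -0.51 in the decile of longest. Corrected for this trend, an alternative added after the data were seen, 983 genes were higher and 1239 lower, and 806 of the 815 calls were shared.

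**Figure D3:**
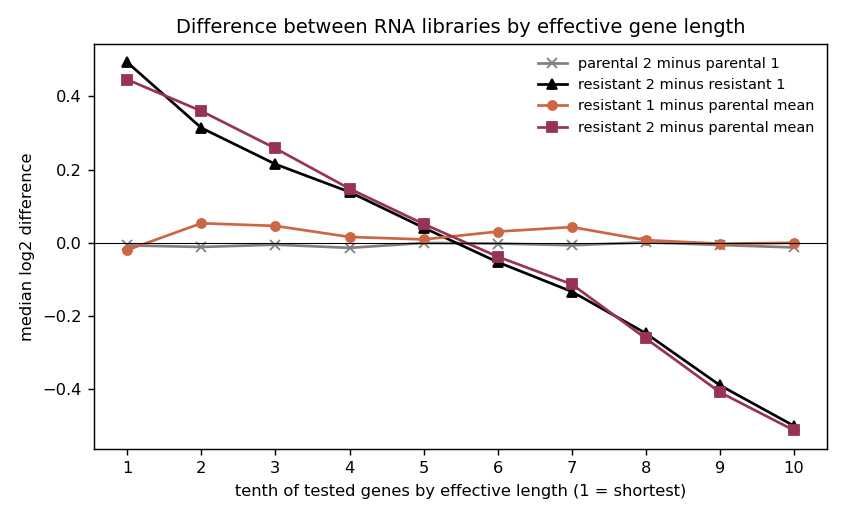
Median log2 difference between RNA libraries in each decile of the tested genes by effective length, from the shortest (1) to the longest (10), with 1 line per comparison. Resistant replicate 2 minus the parental mean runs from 0.45 to -0.51, while resistant replicate 1 minus the parental mean stays between -0.02 and 0.05.

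H3K27ac peaks were compared as presence or absence in 89076 merged regions, of which 19572 had a peak in all 4 libraries. The resistant line gained 3055 regions, with a peak in both resistant libraries and neither parental one, and lost 3496. The split turned to 3338 gained and 2953 lost with the same number of peaks per library, and to 3182 and 3131 where peaks had to cover 50% of a region. In the coordinates of the peak lists (hg19, counted from 1), the gained region with the highest score of its weaker peak was chromosome 7, 1016458 to 1018255, with scores of 35.1 and 21.3. The next were chromosome 15, 100346652 to 100347055, chromosome 1, 38367395 to 38371555, chromosome 1, 235043470 to 235045887, and chromosome 3, 138079149 to 138082502, with weaker scores from 20.7 down to 17.7. The leading lost region was chromosome 7, 102244002 to 102245247, with scores of 44.4 and 37.3. It was followed by chromosome 6, 166073218 to 166075878, chromosome 8, 125763271 to 125766337, chromosome 11, 125932370 to 125933239, and chromosome 19, 56159082 to 56160124, with weaker scores from 29.4 down to 25.4. The scores are the authors' own, and the regions were not matched to genes here. The weaker score was 10 or more in 88 gained and 99 lost regions, and its median was 4.32 in gained, 4.12 in lost and 7.99 in regions found in all 4 libraries.

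Presence in 2 against 2 libraries was not tested, and the other ways to pair the 4 libraries were counted as background. Both replicate 2 libraries alone shared 4132 regions, more than were gained or lost, and both replicate 1 libraries 993, while parental 1 with resistant 2 shared 1931 and parental 2 with resistant 1 shared 1139. The libraries did not group by line when all merged regions of a pair were compared. The parental pair shared 45.02% of its regions and the resistant pair 43.0%. Resistant 2 shared 45.76% with parental 1 and 44.77% with parental 2, while resistant 1 shared 39.65% and 35.08% with them. Replicate 2 peaks were wider in both lines, with medians of 924 and 1041 bp against 674 and 604 bp. Within replicate number 1 alone 20876 regions were gained and 25711 lost, and within replicate number 2 alone 18254 and 21526. Peaks with a score of 5 or more left 1965 gained and 1957 lost regions. Leaving out 1 library, which relaxes the rule for its line, gave 4867 to 14829 gained regions and 4415 to 19271 lost ones. The lowest gained count came without parental replicate 1 and the highest without resistant replicate 2, and the lowest lost count came without resistant replicate 1 and the highest without parental replicate 1.

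**Figure D4:**
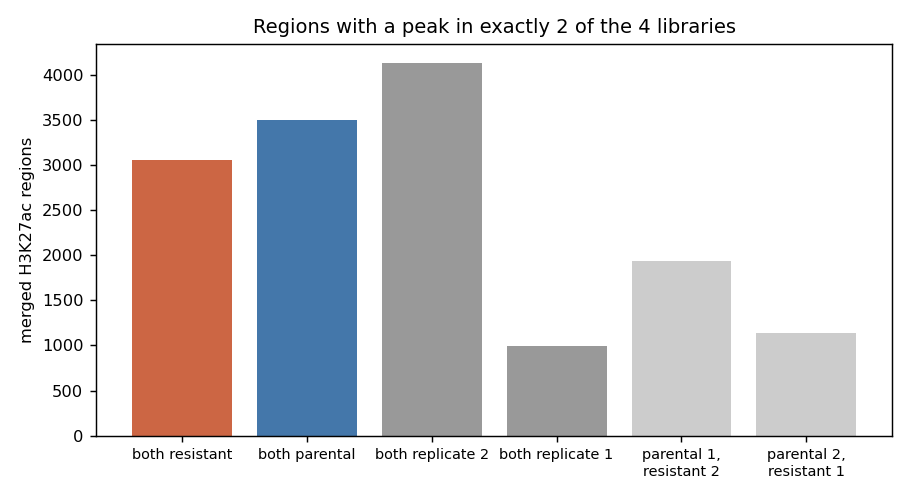
Number of merged H3K27ac regions with a peak in exactly 2 of the 4 libraries, with 1 bar for each pair of libraries. The bar of both resistant libraries stands at 3055, that of both parental libraries at 3496 and that of both replicate 2 libraries at 4132.

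Along chromosome 7 both measurements shifted in blocks of neighbouring genes or regions, a comparison made after the data were seen. Of the first 200 tested genes in gene order, 81 rose and 3 fell, and their median log2 fold change was 0.83, with medians of 0.80 and 0.86 in the resistant libraries. The 3 that fell were AHR, the aryl hydrocarbon receptor (log2 fold change -1.49), IGFBP3 (-3.13) and ITGB8 (-1.17). EGFR, the epidermal growth factor receptor, lies among these genes and stood at 203 ± 2.50 and 286 ± 155 CPM, with 395 and 176 in the resistant libraries (log2 fold change 0.49 ± 0.36, adjusted p = 0.417). The tested genes that follow, from PSPH to IMMP2L, had a median of -0.33, and 16 of them fell and 3 rose. The remaining 167 had a median of 0.01, with 4 higher and 4 lower. Between 0 and 55 Mb of the peak coordinates 165 H3K27ac regions were gained and 17 lost, against 2890 and 3479 elsewhere. In the section that starts at 75 Mb and holds 920 merged regions, 5 were gained and 96 lost. Between these sections, from 55 to 75 Mb, 8 were gained and 11 lost, and in the last section, which holds 1892 merged regions, 75 were gained and 66 lost.

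**Figure D5:**
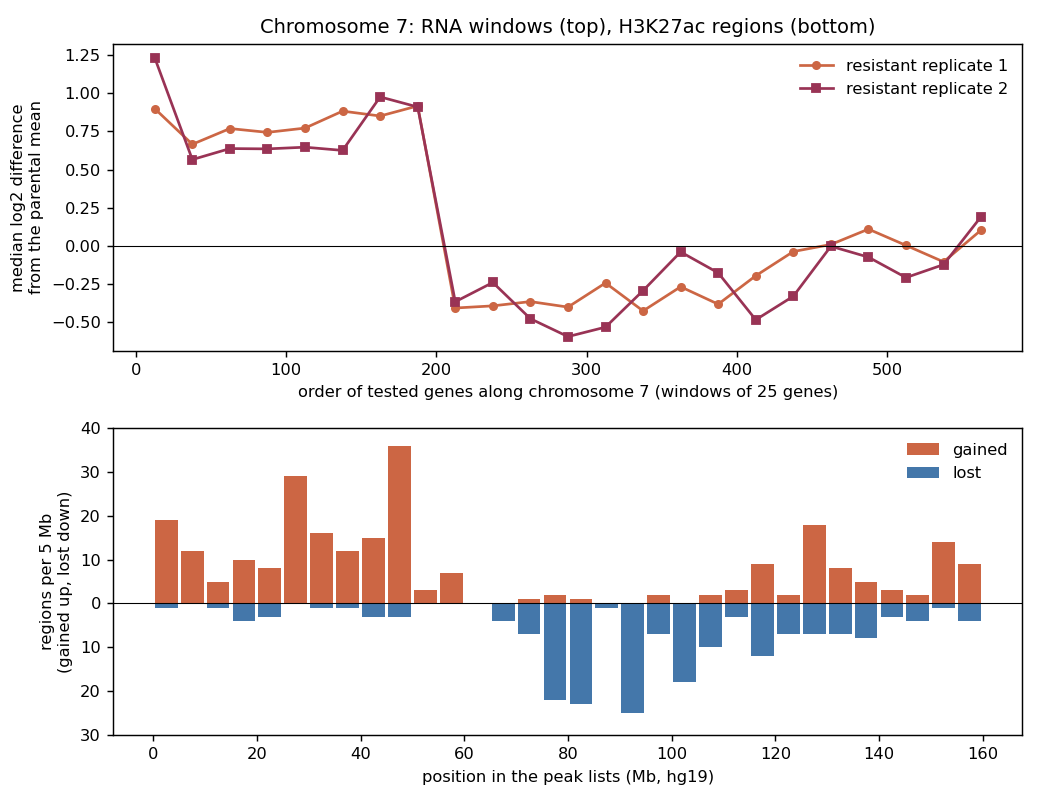
Top, median log2 difference of each resistant RNA library from the parental mean in windows of 25 tested genes along chromosome 7; bottom, H3K27ac regions gained (up) and lost (down) per 5 Mb of the peak coordinates (hg19). The first 200 genes have medians of 0.80 and 0.86 in the resistant libraries, and 165 regions were gained and 17 lost between 0 and 55 Mb.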

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

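Sample quality weights, the length correction and single replicate numbers of the peaks were chosen after the data were seen. The numbers of genes higher and lower were 576 and 715 with DESeq2's Wald test, 790 and 819 with sample quality weights and 983 and 1239 after length correction. The numbers higher, lower, and higher and lower by 2-fold or more were 242, 283, 159 and 217 with limma-trend on log2(TPM + 1), 216, 244, 149 and 195 on log2(TPM + 0.1), and 24, 73, 24 and 73 at a threshold of 0.01, a stricter threshold by construction. With a replicate block they were 860, 1020, 463 and 551. Deviations of libraries with the same number had a correlation of -0.046, so no pairing was established. Leaving out 1 library gave 141 to 3374 genes higher, 264 to 3479 lower, 141 to 723 higher by 2-fold or more and 264 to 969 lower by 2-fold or more. Without a resistant library the spread came from the closely matched parental pair alone. For the other settings the cause was not tested.

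AXL kept its direction under every alternative run and passed the threshold with DESeq2 (log2 fold change -0.57), sample quality weights (-0.56) and length correction (-0.41), and its fold change without 1 library was -0.62 to -0.51. MET kept its direction and was -0.76 to -0.13 without 1 library. Of 26 lists 0 passed with an estimated correlation and 4 with fry (mesenchymal genes, growth factor ligands, blood, endothelial and stromal markers, and AXL and MET receptors), and 10 to 13 under the other alternatives at 0.05. B2M was 0.14 without resistant replicate 1 and -0.20 without resistant replicate 2, and the cause was not tested. Length correction ended the list calls of NRF2 targets (adjusted p = 0.0563) and growth factor ligands (0.0701) and brought p53 targets past the threshold, lower (0.0224). Growth factor ligands also did not pass with limma-voom (0.0786), sample quality weights (0.0715) or a replicate block (0.0754). The list of AXL and MET receptors passed, lower, with DESeq2's Wald test (0.0399), and epithelial genes passed, lower, with that test (0.00522), library totals (0.0378), no filter (0.0263), the stricter filter (0.0126) and a replicate block (0.0116). Of 62 called genes that the rule for named genes took, 24 passed at a threshold of 0.01. At 0.05, 44 kept their call under all other alternatives fixed beforehand that gave a value, apart from left-out libraries, and 18 did not pass in at least 1. Of the 62, 44 kept their call without each library in turn, and 18 lost it without a parental one. None of the 62 reversed. Of 9 reported genes of the same rule that were not called, other than AXL and MET, 8 passed without a resistant library and 1 of these, B2M, reversed. Called genes named after their values were seen were not counted.

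The excess of lost over gained regions did not hold with the same number of peaks per library (3338 gained and 2953 lost). It did not hold with cover of 50% of a region (3182 and 3131) or a score of 5 or more (1965 and 1957) either. Merging within 500 bp kept it (2742 and 3196). Gained and lost regions were 20876 and 25711 in replicate number 1 alone, and 18254 and 21526 in replicate number 2 alone, which ask for 1 library per line. Leaving out 1 library gave 4867 to 14829 gained and 4415 to 19271 lost regions. The planned test of genes near gained and lost regions and its alternatives were not run, for want of a gene table in the build of the peaks. At the depth of these libraries 46% of genes simulated with a 2-fold change were called, and no other depth was simulated. That share holds for genes above a minimum level and for the same spread in both lines.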

Other observations

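The tests for gene blocks, for the neighbours of AXL and for the preparation of resistant replicate 2 were chosen after the result was seen. Along the chromosomes 12 of 496 windows of up to 25 neighbouring genes had a median log2 fold change outside the range of 1000 shuffled gene orders (-0.59 to 0.64), 8 of them at the start of chromosome 7, and both resistant libraries lay on the same side in all 12. Chromosome 19 held 3 with low medians, from ZNF382 to KCNK6 (-0.62), from ZNF524 to ZNF419 (-0.64) and from ZNF773 to ZNF837 (-0.68). They were part of a longer run. Every window of chromosome 19 from ZNF714 onwards had a negative median, and every earlier one a positive median. The window of AXL, from ITPKC to CIC (-0.44), lay in that run. Other chromosomes had long runs of negative medians too, such as chromosome 2 (SH3YL1 to SLC35F5), chromosome 3 (ROBO1 to LMLN) and chromosome 6 (NFYA to PDCD2). On chromosome X the window from LAGE3 to VAMP7 had a median of 0.68. By chromosome, the share of gained among gained and lost H3K27ac regions was highest on chromosome 22 (78.4%, 69 gained and 19 lost) and lowest on chromosome 6 (23.9%, 90 and 286), with median RNA log2 fold changes of 0.20 and -0.10.

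AXL and MET mRNA were lower in the resistant libraries, without passing the threshold over all genes, and this may have technical sources. After correction for effective length AXL was at -0.41 ± 0.11 (SE) and MET at -0.22 ± 0.10, each more than 2 SE below 0. The correction cannot decide for either gene, since a trend in replicate 2 alone lets it move the group value only in part. Resistant replicate 1, nearly without that trend, differed from the parental mean by -0.50 for AXL. That value argues against the length trend of resistant replicate 2 as the whole source of the AXL difference. The value of MET moved from -0.41 and still did not pass (adjusted p = 0.186). MET lay at -0.13 in resistant replicate 1 and at -0.77 in replicate 2. Under the other scalings the highest log2 fold change of AXL was -0.48 ± 0.14, so the choice among them was not the source of its fall. They moved the median log2 fold change of all tested genes only from 0.02 to 0.01 and 0.10. A larger scaling error is not covered by this. The 24 neighbours of AXL in its window had a median of -0.42 (quartiles -0.57 and -0.19), and the share of 10000 random sets of genes with so low a median was 3e-04, so a shift shared with the neighbouring genes stays open. Drug exposure, medium and selection differ together between the lines and stay open as well.

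Transcript levels in resistant replicate 2, relative to replicate 1, fell with effective gene length. After thinning replicate 1 to the depth of replicate 2 the rank correlation was still -0.59. Thinning removes counts at the same rate from every gene, so this bears only on the number of counts sampled. The trend was present against the parental mean too (-0.46) and nearly absent in replicate 1 (-0.013), so a difference in RNA or library preparation of replicate 2 is a candidate explanation. The NF-kB list was lower in replicate 2 than in replicate 1 by a median of -1.29 before and -1.19 after correction (bootstrap SE 0.26), so the length trend is not its whole source. A biological difference between the resistant libraries was not tested and stays open.

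Expression shifted in blocks of neighbouring genes. The SD of window medians was 0.25, against at most 0.13 in shuffled orders and 0.044 between the parental libraries, which argues against a chance order of genes. After length correction the first 200 tested genes of chromosome 7 had a median of 0.82. Their median was 0.80 in resistant replicate 1, which nearly lacks the length trend. The value of replicate 1 argues against that trend as the source of this block. The corrected value cannot decide, since the correction moves the group median only in part. For other blocks taken singly this was not tested, and the SD of all window medians was 0.24 after correction. Over 23 chromosomes the gained share of H3K27ac regions rose with the median RNA log2 fold change (Spearman correlation 0.838, Pearson r = 0.841; two-sided permutation p = 1e-05 for both, the smallest that 100000 permutations can give). Pearson r was 0.79 without chromosomes 10 and 12, the farthest from the median RNA change. A copy-number difference between the lines is therefore a hypothesis that these values would allow, but regional regulation would give the same relation, and the DNA inputs that could separate them were not analysed here.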
